A study of Mus musculus with 12 samples.

How the data were processed

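Striatal RNA of 12 mice was measured on Affymetrix mouse expression arrays with biotin-labelled RNA, 1 array per mouse. The labels gave genotype, age, sex and an animal number for each mouse, and the arrays were grouped by genotype and age into 4 groups of 3 (wild type and Q92, at 3 and at 18 months). The wild-type groups held 1 female and 2 males at 3 months and 2 females and 1 male at 18 months, and both Q92 groups held 2 females and 1 male. The deposited values are log2 signals per probe set, and the submitters' processing notes name RMA, which corrects background, normalises arrays to a common distribution and summarises the probes of a probe set, and the affy package, both without a version. Whether the authors normalised the 12 arrays together is not given in the sources used here. RMA removes differences in total signal between arrays, so a difference between groups is relative to the other genes of the array, and a change in the cell composition of the dissected tissue appears as a change in expression. The values ran from 2.03 to 13.8 and were used as deposited, with no further normalisation or filter in the main analysis. Array data give no read depth, and the number of arrays limits the precision (the median SE of a log2 difference was 0.122, and 0.172 for the change of the genotype difference with age).

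All comparisons were made with limma 3.58.1 in R 4.3.3. One model with a mean per group was fitted to the 12 arrays, so that all groups shared 1 estimate of the spread (8 residual and 4.50 prior degrees of freedom), and moderated tests were taken for 5 contrasts. They were Q92 against wild type at 18 months and at 3 months, the change of this difference with age, and 18 against 3 months in wild type and in Q92. P-values were adjusted by the Benjamini-Hochberg method over the 45037 probe sets within each contrast, and 0.05 was the threshold. Counts are of probe sets, with the number of distinct genes beside them. The 64 control probe sets were left out of these tests.

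Gene names came from the probe table given with the series. It paired 34945 probe sets with 1 gene and 932 with several, and 9160 had no name. Of the named probe sets, 34741 had a gene identifier that was found in the RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order only, and 0 symbols changed. A gene was represented by the probe set with the highest mean over all 12 arrays among those paired with that gene alone, which gave 18193 genes. The genes named in the text followed a rule. In each contrast these were the 10 genes with the largest increase and the 10 with the largest decrease among those that passed and whose 3 arrays of one group lay entirely above those of the other, or, where under 5 passed, the 5 with the smallest p as values only. Htt was named throughout, as were up to 4 members with the largest difference from each list that passed and from the 3 striatal neuron lists, and 10 genes of those lists in the genotype contrasts (Drd1, Drd2, Adora2a, Penk, Pdyn, Tac1, Ppp1r1b, Pde10a, Cnr1 and Rgs9). Genes outside the rule are named as such.

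There were 22 gene lists with 400 genes, 371 of them measured, fixed from general knowledge of the tissue. They cover projection neuron identity, indirect pathway neuron, direct pathway neuron, activity-regulated immediate early genes, cholesterol biosynthesis, heat shock and chaperones, oxidative phosphorylation, proteasome, astrocyte, reactive astrocyte, microglia, MHC class I and interferon response, oligodendrocyte, oligodendrocyte precursor, vascular, collagen and matrix, choroid plexus and ependyma, cortical excitatory neuron, thalamic and pallidal neuron, striatal interneuron, neurogenesis and proliferation, and erythrocyte. Lists were tested with limma's camera with its preset correlation between genes of 0.01, adjusted over the 22 lists within a contrast, and again with camera with an estimated correlation and with fry. Camera compares a list with all other genes, and fry tests whether the genes of a list move, on balance, one way.

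The groups, contrasts, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. These alternatives were quantile normalisation, a shift of each array to a common median, leaving out probe sets at or below the 40th percentile of mean signal, an intensity trend with a robust prior, array weights, sex as a covariate, a fit to only the arrays compared, 1 probe set per gene, the mean of all probe sets of a gene, and leaving out each array in turn. Covariates for an 18S ribosomal RNA control probe set, for cortical and thalamic marker genes and for choroid plexus marker genes, leaving out both arrays with the lowest mean correlation, and a block for age in days within each age (genotype contrasts only), were added after the data had been seen. An alternative for values on a linear scale was not run because the values are on a log2 scale.

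Xist and Eif2s3y separated the sexes as the labels gave them in 12 of 12 arrays, and 0 pairs of arrays held identical values. The procedure was tested on simulated data with the group sizes of each comparison, 45037 probe sets and, for each probe set, the moderated spread that all groups share. Moderation draws the spread of a probe set towards a common value, so the most variable probe sets were simulated with less spread than they showed. Probe sets were drawn independently and with equal spread in all arrays. The shares below therefore do not cover correlation between genes or arrays that vary more than others. In each simulation 200 probe sets were changed at once, 100 of them 2-fold and 100 of them 4-fold. Where fewer change, the adjustment is stricter and the share recovered would be lower. Of 100 probe sets changed 2-fold it recovered 93% for the genotype contrast at 18 months, 94% at 3 months, 71% for the change with age, 96% for wild-type ageing and 95% for Q92 ageing. Of 100 changed 4-fold it recovered 98% to 100%, and unchanged probe sets made up 4.88% to 9.35% of the calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.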

Results

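Gene expression was measured in the striatum of 12 mice with Affymetrix mouse expression arrays, 1 array per mouse. The striatum is a forebrain nucleus made up mostly of GABAergic projection neurons, the neurons most affected in Huntington's disease. Q92 mice carry a knock-in of 92 CAG repeats in Htt (older symbol Hdh), the mouse counterpart of the human disease gene. The 12 mice formed 4 groups of 3, namely wild-type and Q92 mice at 3 months (100 to 103 days) and at 18 months (567 to 604 days). The labels gave each mouse its own number, so the replicates were separate animals, and mice are named here by group and number (wt for wild type, m for months). Of the 45101 probe sets, 45037 were tested and 64 control probe sets were left out. The precision was limited by the 3 arrays per group. Correlations between arrays ran from 0.983 to 0.995, and the mean correlation with the other arrays was lowest in mouse wt_3m_467 at 3 months (0.987) and mouse Q92_18m_66 at 18 months (0.988). Values are log2 signals, given as mean ± SD with n = 3 mice per group unless stated, and differences are Q92 minus wild type or 18 minus 3 months.

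Htt itself was given first because it carries the knock-in. Its brightest probe set read 7.85 ± 0.14 in Q92 and 7.75 ± 0.06 in wild-type mice at 18 months, a log2 difference of 0.10 (SE 0.10, adjusted p = 0.883). At 3 months it read 8.06 ± 0.03 against 7.76 ± 0.14, a log2 difference of 0.30 (SE 0.10, adjusted p = 1.00). None of the 4 Htt probe sets passed the threshold in any of the 5 comparisons.

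The first question was how Q92 striatum differed from that of wild-type mice at 18 months. The Q92 mice were 567 to 596 days old and the wild-type mice 596 to 604 days, so genotype partly coincided with age in days. Penk, which encodes the enkephalin precursor made by striatal neurons of the indirect pathway, fell 2.39-fold (10.37 ± 0.20 against 11.63 ± 0.06). Ryr1, an intracellular calcium release channel, fell 3.24-fold, and Ddit4l, an inhibitor of mTOR signalling, fell 2.33-fold. Among the few genes that were higher, Speer4cos rose 5.21-fold, Abhd1 rose 2.77-fold and Rrs1, a ribosome biogenesis factor, rose 1.60-fold.

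In this comparison 24 of 45037 probe sets passed an adjusted p of 0.05 in limma, 7 of them higher (5 genes) and 17 lower (14 genes) in Q92 mice. An unadjusted p under 0.05 was reached by 3560 probe sets, where 2252 would be reached by chance. Besides Penk (log2 difference -1.26, SE 0.11, adjusted p = 0.00113), the genes that fell were Cfap54 (-1.98, adjusted p = 0.0109), Sdr39u1 (-1.74, adjusted p = 0.00170), Ryr1 (-1.70, adjusted p = 0.0144) and Clspn (-1.40, adjusted p = 0.00113), which encodes the checkpoint adaptor claspin. Fst, the activin-binding protein follistatin, fell by 1.38 (adjusted p = 0.0274), and Ddit4l fell by 1.22 (adjusted p = 0.0109), with all 3 of its probe sets lower past the threshold. Rspo1, a Wnt agonist, fell by 1.15 (adjusted p = 0.0467), Neto2, an auxiliary subunit of kainate receptors, by 0.91 (adjusted p = 0.0109), and the transcriptional cofactor Lmo2 by 0.85 (adjusted p = 0.0402). The log2 increase was 2.38 for Speer4cos (SE 0.15, adjusted p = 6.18e-05), 1.47 for Abhd1 (SE 0.15, adjusted p = 0.00170) and 0.67 for Rrs1 (SE 0.09, adjusted p = 0.0191). Penk, Clspn, Sdr39u1, Abhd1 and Speer4cos passed without any single array. The calls of 8 of these 13 genes ended without mouse wt_18m_9 (9 probe sets left), of 5 without mouse Q92_18m_66, of 4 without mouse wt_18m_12, of 3 each without mouse wt_18m_17 and mouse Q92_18m_11, and of 2 without mouse Q92_18m_25, with adjusted p between 0.0523 and 0.195. With the signal of an 18S ribosomal RNA control probe set as a covariate 8 probe sets passed, and with only the 6 arrays compared 11 passed, 8 and 9 of them among the 24. In each of these settings 8 of the 13 named genes lost their calls (adjusted p from 0.0536 to 0.194). Lmo2 (0.0684) and Rspo1 (0.0762) also lost them with sex as a covariate. Blocking mice by age in days rests the comparison on 2 wild-type mice and 1 Q92 mouse of the same age and leaves 4 residual degrees of freedom. When blocked, 4 passed, 1 of them among the 24 (Speer4cos, adjusted p = 0.0367), and Penk differed by -1.26 (adjusted p = 0.0978).

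**Figure D1:**
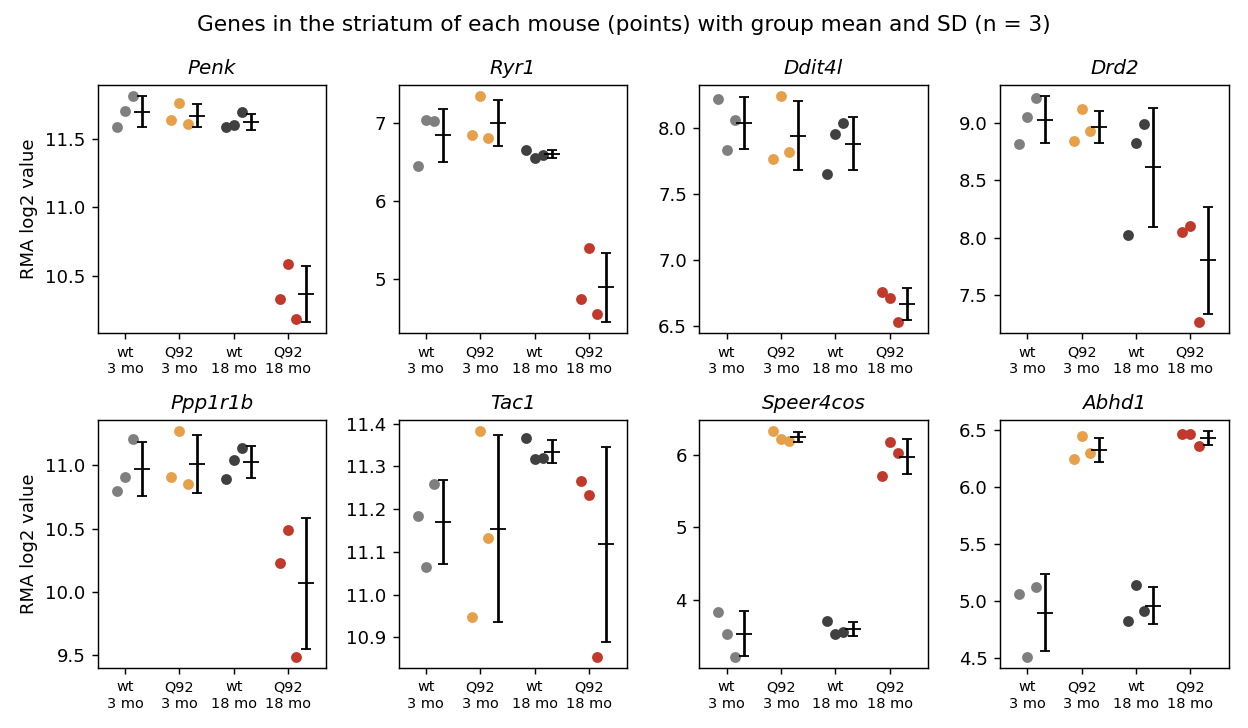
Log2 signal (y axis, RMA) of 8 genes in each mouse, by group (x axis); points are mice, horizontal bars group means and vertical lines 1 SD, n = 3. Penk, Ryr1 and Ddit4l were lower in all 3 Q92 mice at 18 months than in all 3 wild-type mice, and Speer4cos and Abhd1 were higher in Q92 mice at both ages.

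Genes that mark striatal projection neurons were lower as a group in Q92 mice at 18 months. All 33 measured genes of the projection neuron identity list had lower means, with a median log2 difference of -0.65 (camera adjusted p = 1.67e-38, fry adjusted p = 0.0331, and adjusted p = 0.145 with an estimated correlation). Of these 33 genes, 1 (Ryr1) passed over all probe sets and 30 passed adjusted over the list alone. The largest differences after Ryr1 did not pass over all probe sets: -1.48 for the sodium channel subunit Scn4b (adjusted p = 0.0557), -1.07 for the G protein regulator Rgs9 (adjusted p = 0.0868) and -1.01 for the adenylyl cyclase Adcy5 (adjusted p = 0.123). Ppp1r1b, which encodes DARPP-32, differed by -0.96 (adjusted p = 0.180), the cannabinoid receptor gene Cnr1 by -0.89 (adjusted p = 0.157) and the phosphodiesterase gene Pde10a by -0.64 (adjusted p = 0.389) at its brightest of 5 probe sets. Another Pde10a probe set, singled out after its values were seen, passed with a log2 difference of -1.18 (adjusted p = 0.0467).

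The markers of the 2 projection pathways differed in size. All 6 measured indirect pathway genes were lower, with a median of -0.90 (camera adjusted p = 1.76e-07, fry adjusted p = 5.31e-04, and adjusted p = 0.0137 with an estimated correlation). Penk passed over all probe sets and 4 of the 6 passed adjusted over the list alone. The receptor genes Gpr6 (-1.05, adjusted p = 0.0557) and Drd2 (-0.81, adjusted p = 0.390) and the metabolic gene Upb1 (-0.98, adjusted p = 0.130) did not pass over all probe sets. Adora2a had no probe set of its own among those used. Of 9 direct pathway genes, 6 were lower and 3 higher, with a median of -0.22 (camera adjusted p = 0.0134, and adjusted p = 0.371 with an estimated correlation), none past the threshold over all probe sets and 3 adjusted over the list alone. The dopamine receptor gene Drd1 differed by -0.88 (adjusted p = 0.262), the muscarinic receptor gene Chrm4 by -0.71 (adjusted p = 0.756), Slc35d3 by -0.64 (adjusted p = 0.295) and the dynorphin precursor gene Pdyn by -0.55 (adjusted p = 0.130). Tac1, the substance P precursor, differed by -0.22 (adjusted p = 0.741). The mean of the indirect pathway genes minus the mean of the direct pathway genes was lower in Q92 mice, by -0.41 (SE 0.05, 95% confidence interval -0.53 to -0.29, exact permutation p = 0.1, two-sided, the smallest that 3 mice against 3 allow). This contrast of the 2 lists was chosen only after the result was seen. The difference of Chrm4 was -0.12 without mouse wt_18m_9 and -0.39 without mouse Q92_18m_66, and that of Slc35d3 was -0.41 without mouse Q92_18m_66. Without mouse wt_18m_9 the direct pathway median was -0.12 (adjusted p = 0.0475). The direct pathway call ended without mouse Q92_18m_66 (median -0.09, adjusted p = 0.156) and with mice blocked by age in days (median -0.08, adjusted p = 0.421).

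Beside the neuronal genes, 10 further lists passed with the preset correlation of 0.01 at 18 months, and none of these calls held with an estimated correlation. Proteasome subunit genes were slightly higher (30 of 31, median 0.13, camera adjusted p = 2.78e-07, and adjusted p = 0.371 with an estimated correlation). Cholesterol biosynthesis genes were higher in 15 of 19 (median 0.08, adjusted p = 0.0330, and adjusted p = 0.383 with an estimated correlation). Markers of cortical excitatory neurons, which lie outside the striatum, were higher in 13 of 15 (median 0.28, adjusted p = 0.00107, and adjusted p = 0.383 with an estimated correlation). The activity-regulated immediate early genes were lower in 15 of 20 (median -0.33, adjusted p = 5.70e-04, and adjusted p = 0.390 with an estimated correlation), among them Egr2 (-1.01, adjusted p = 0.391) and Npas4 (-1.01, adjusted p = 0.547). None of the members of these 4 lists passed over all probe sets or adjusted over the list alone. The glial, vascular and immune lists were lower. They were astrocyte (15 of 16, median -0.21, adjusted p = 1.65e-05), reactive astrocyte (11 of 14, -0.28, adjusted p = 7.10e-04), microglia (17 of 19, -0.31, adjusted p = 7.47e-05), MHC class I and interferon response (17 of 17, -0.47, adjusted p = 4.09e-05), oligodendrocyte (15 of 17, -0.14, adjusted p = 1.10e-04) and vascular (15 of 15, -0.16, adjusted p = 3.72e-04). With an estimated correlation, adjusted p was 0.279 for astrocyte, 0.371 for vascular, 0.390 for MHC class I and interferon response, and 0.383 for reactive astrocyte, microglia and oligodendrocyte. No member of these 6 lists passed over all probe sets. Adjusted over the list alone, 1 astrocyte, 1 reactive astrocyte, 2 oligodendrocyte and 1 vascular gene passed. Examples are the astrocyte bicarbonate transporter gene Slc4a4 (-0.45, adjusted p = 0.144), the complement gene C1qc (-0.72, adjusted p = 0.368), the interferon-induced Usp18 (-1.31, adjusted p = 0.569, and -0.71 without mouse wt_18m_17) and the myelin gene Mal (-0.55, adjusted p = 0.262). Lists that did not pass were oxidative phosphorylation (median 0.03, adjusted p = 0.0777), oligodendrocyte precursor (-0.18, adjusted p = 0.0795), heat shock and chaperones (0.04, adjusted p = 0.0927), thalamic and pallidal neuron (-0.21, adjusted p = 0.108), striatal interneuron (-0.24, adjusted p = 0.254), choroid plexus and ependyma (-0.30, adjusted p = 0.337), collagen and matrix (-0.13, adjusted p = 0.459), neurogenesis and proliferation (0.02, adjusted p = 0.841) and erythrocyte (-0.00, adjusted p = 0.904, with the test in the upward direction and the mean at -0.01).

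Several of these lists followed single mice within the groups at 18 months. Relative to the mean of the 12 arrays, the cortical list averaged 0.74 in mouse Q92_18m_11 and 0.65 in mouse Q92_18m_25 but -0.44 in mouse Q92_18m_66, and the thalamic and pallidal list averaged 0.92 in mouse Q92_18m_66. The MHC class I and interferon list averaged 1.66 in mouse wt_18m_17 and 0.91 in mouse Q92_18m_66, and the choroid plexus list averaged 1.69 in mouse wt_18m_12. The projection neuron identity list averaged -0.96 in mouse Q92_18m_66, -0.48 in mouse Q92_18m_11 and -0.33 in mouse Q92_18m_25, all below the 3 wild-type mice (0.05 to 0.19). An 18S ribosomal RNA control probe set read 7.35 ± 1.06 in Q92 and 5.71 ± 0.06 in wild-type mice. Without mouse Q92_18m_25, 8 lists passed and those for reactive astrocyte (adjusted p = 0.0933), microglia, vascular and cortical neuron (0.0749 each), MHC class I and interferon (0.0670) and cholesterol biosynthesis (0.114) did not. The cortical list also failed without mouse Q92_18m_11 (median 0.14, adjusted p = 0.433), as did cholesterol biosynthesis (median 0.03, 0.463) and oligodendrocyte (median -0.00198, 0.0521). The MHC list failed without mouse wt_18m_17 (median -0.10, 0.513), the immediate early genes failed without mouse Q92_18m_66 (median -0.05, 0.791), and cholesterol biosynthesis failed without mouse wt_18m_12 (0.131) or wt_18m_17 (0.0722). Other calls held with a changed median. Without mouse Q92_18m_66 the median was 0.07 for proteasome, -0.70 for microglia, -0.81 for MHC class I and interferon, -0.25 for oligodendrocyte and 0.71 for cortical genes. It was -0.17 for microglia without mouse wt_18m_17, -0.89 for MHC class I and interferon without mouse wt_18m_9, and -0.52 for immediate early and -0.26 for oligodendrocyte genes without mouse Q92_18m_25. With mice blocked by age in days the immediate early genes (0.359) and the vascular list (0.116) failed.

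**Figure D2:**
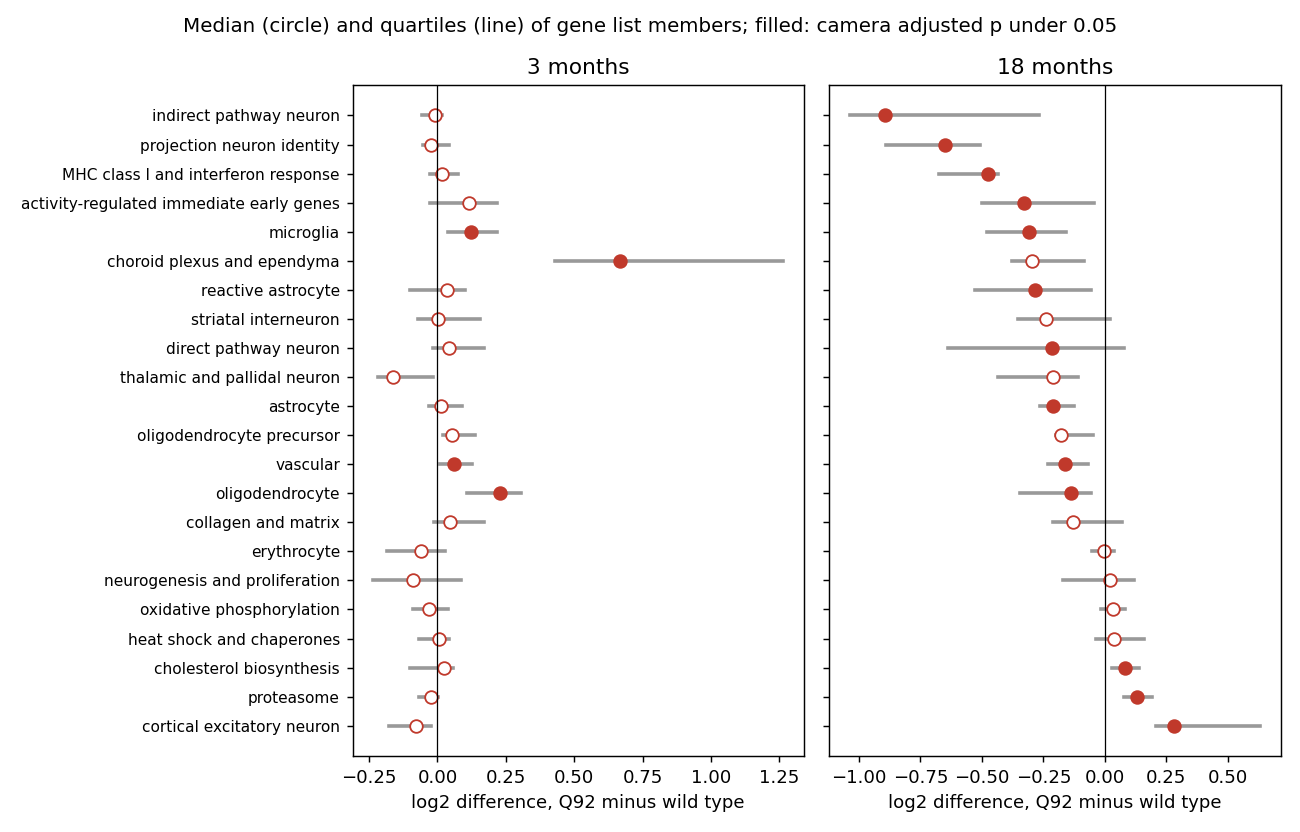
Log2 difference, Q92 minus wild type (x axis), of the members of 22 gene lists (y axis) at 3 months (left) and 18 months (right); circles are list medians, lines span the quartiles, and filled circles passed camera with the preset correlation. The medians of the indirect pathway (-0.90) and projection neuron (-0.65) lists were the lowest at 18 months, while those at 3 months were -0.01 and -0.02.

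At 3 months the question was whether the same genes already differed in young Q92 mice. No gene of the striatal neuron lists passed the test. Penk read 11.67 ± 0.08 in Q92 and 11.70 ± 0.11 in wild-type mice. Speer4cos rose 6.60-fold (6.25 ± 0.07 against 3.53 ± 0.31), Abhd1 rose 2.70-fold and Rrs1 rose 1.71-fold, the genes that were also higher at 18 months.

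In limma 5 of 45037 probe sets passed, 4 higher and 1 lower, and 1191 reached an unadjusted p under 0.05, where 2252 would by chance. Probe sets are not independent, so such counts can lie well above or below that number. The rule for named genes gave 5 genes by smallest p. Their log2 differences were 2.72 for Speer4cos (SE 0.15, adjusted p = 1.24e-05), 1.43 for Abhd1 (adjusted p = 0.00660), 0.77 for Rrs1 (adjusted p = 0.0161), and 0.67 for Ggps1 and 0.48 for Elk3, neither of which passed (adjusted p = 1.00). The other 2 probe sets that passed belonged to Ppp1cb (higher) and Jakmip1 (lower), named here after their values were seen. At 18 months the same Ppp1cb probe set differed by 1.54 (adjusted p = 0.00113) and the Jakmip1 probe set by -1.83 (adjusted p = 0.00170). All 5 probe sets were also called at 18 months, in the same direction, where chance would give 0.00266 shared. Of the 5 genes, Abhd1, Ppp1cb, Jakmip1 and Speer4cos lie on the chromosome of Htt, with 65, 33, 29 and 173 measured genes between each of them and Htt. Rrs1 lies on another chromosome. The count was 1 without mouse Q92_3m_439 or mouse Q92_3m_440, 3 without mouse wt_3m_436 or mouse Q92_3m_466, 1 with only the 6 arrays compared and 2 with mice blocked by age in days, both among the 5. Speer4cos passed in each of these, while the call of Rrs1 ended without any 1 of the 6 arrays (adjusted p 0.0804 to 0.167) and that of Abhd1 without mouse Q92_3m_439 (0.0545) or Q92_3m_440 (0.0626). Both calls ended when blocked (adjusted p = 0.395 for Rrs1 and 0.242 for Abhd1) and with only the 6 arrays compared (0.206 for each).

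**Figure D3:**
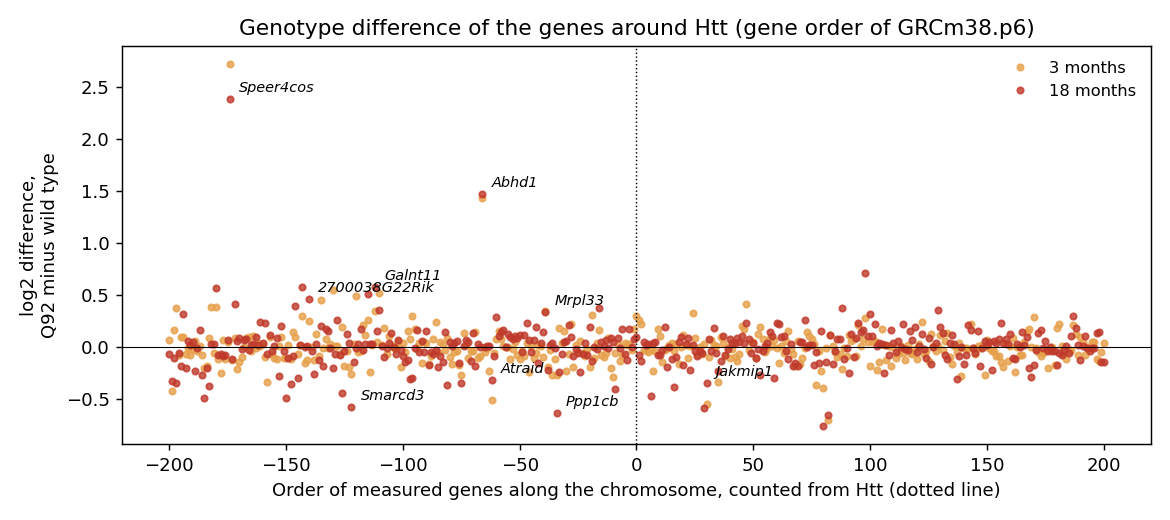
Log2 difference, Q92 minus wild type (y axis), of the 401 measured genes around Htt in gene order (x axis, dotted line at Htt), at 3 months (orange) and 18 months (red), each gene by its brightest probe set. Speer4cos (2.72 and 2.38) and Abhd1 (1.43 and 1.47) stood apart at both ages.

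Among gene lists at 3 months, the projection neuron identity list had a median of -0.02 (13 of 33 higher, camera adjusted p = 0.830 in the upward direction, which differs in sign from the median), the indirect pathway list -0.01 (3 of 6 higher, adjusted p = 0.976, also in the upward direction) and the direct pathway list 0.04 (5 of 9 higher, adjusted p = 0.543). The members with the largest differences were Pde2a (-0.23) and Ryr1 (0.16) for projection neurons, Gpr6 (-0.12) and Drd2 (-0.06) for the indirect pathway, and Chrm4 (0.64) and Sfxn1 (-0.30) for the direct pathway, all with adjusted p = 1.00, and Chrm4 was at 0.32 without mouse wt_3m_436. The differences of Drd1 (0.23), Ppp1r1b (0.04), Pde10a (0.03), Pdyn (-0.04), Cnr1 (-0.04), Tac1 (-0.02) and Rgs9 (-0.01) had the same adjusted p. The 4 lists that passed with the preset correlation were all higher in Q92 mice, namely oligodendrocyte (17 of 17, median 0.23, adjusted p = 9.78e-10), choroid plexus and ependyma (13 of 14, 0.67, adjusted p = 1.33e-05), microglia (15 of 19, 0.12, adjusted p = 0.00456) and vascular (13 of 15, 0.06, adjusted p = 0.0219). For each of the 4, adjusted p = 0.978 with an estimated correlation. The choroid plexus list averaged 1.80 in mouse Q92_3m_439, and without that mouse its median was 0.00 (adjusted p = 0.715). The microglia call ended with sex as a covariate (adjusted p = 0.0701), and without mouse wt_3m_436 (0.0931) or mouse Q92_3m_440 (0.0981). The vascular call ended without mouse wt_3m_436 (median -0.01, 0.900), mouse Q92_3m_440 (0.0981) or mouse Q92_3m_466 (0.0651), and 7 lists passed without mouse wt_3m_438. The oligodendrocyte median was 0.10 without mouse wt_3m_467, the vascular median was 0.13 without mouse wt_3m_438 and 0.10 without mouse Q92_3m_439, and the choroid plexus median was 1.16 without mouse Q92_3m_440 and 1.08 without mouse Q92_3m_466. The other 15 lists had adjusted p from 0.110 to 0.970, and 1 oligodendrocyte gene and no other list member passed adjusted over the list alone.

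Whether the genotype difference itself changed with age was tested as the difference at 18 months minus that at 3 months. For Penk the genotype difference was -1.26 at 18 months and -0.03 at 3 months, which differed by -1.22 (SE 0.16). For Sdr39u1 the 2 differences were apart by -1.94 (SE 0.25) and for Clspn by -1.44 (SE 0.18). None of these passed in limma over all probe sets (adjusted p = 0.0598 for each of the 3).

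In limma 0 of 45037 probe sets passed, and 2335 reached an unadjusted p under 0.05, where 2252 would by chance. Cfap54 (-2.07) and Ryr1 (-1.85) came next (adjusted p = 0.300 for both). With an intensity trend and a robust prior 3 probe sets passed, those of Penk (adjusted p = 0.0116), Sdr39u1 (0.0311) and Clspn (0.0412), and with 1 probe set per gene the same 3 genes passed (adjusted p = 0.0197 each). Array weights gave 2, the cortical and thalamic lists as covariates gave 1, blocking by age in days gave 1, and leaving out single arrays gave 3 without mouse Q92_18m_25, 2 without mouse wt_18m_17 and 1 without mouse Q92_18m_11.

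The genotype difference of all 33 projection neuron identity genes was lower at 18 than at 3 months (median -0.68, camera adjusted p = 1.75e-28, and adjusted p = 0.220 with an estimated correlation), with 0 genes past the threshold over all probe sets and 18 adjusted over the list alone. All 6 indirect pathway genes were lower (median -0.84, adjusted p = 1.45e-06, fry adjusted p = 0.00914, and adjusted p = 0.0247 with an estimated correlation), 3 of them adjusted over the list alone. Of the 9 direct pathway genes 5 were lower (median -0.20, adjusted p = 0.00842, and adjusted p = 0.287 with an estimated correlation), 2 of them adjusted over the list alone. In all, 14 of 22 lists passed with the preset correlation, 2 higher (proteasome and cortical excitatory neuron) and 12 lower. Only the indirect pathway list held with an estimated correlation, the other 13 having adjusted p from 0.220 to 0.410. All 17 oligodendrocyte genes (median -0.42), all 19 microglia genes (-0.42) and all 14 choroid plexus genes (-0.87) were lower, in each case with the higher value at 3 months adding to it. The choroid plexus call ended without mouse Q92_3m_439 (adjusted p = 0.245) or mouse wt_18m_12 (0.313), the cortical call without mouse Q92_18m_11 (0.234) or Q92_18m_25 (0.0516), the MHC class I and interferon call without mouse wt_18m_17 (0.299), and the immediate early gene call without mouse Q92_18m_66 (0.196). The direct pathway call ended without mouse Q92_18m_66 (0.0672) or Q92_3m_440 (0.0518) and when blocked by age in days (0.161), as did the immediate early gene call when blocked (0.0872). The reactive astrocyte call ended without mouse wt_18m_17 (0.0570) or mouse Q92_18m_25 (0.0924), and the oligodendrocyte precursor call ended without mouse Q92_18m_11 (0.0573), mouse Q92_18m_25 (0.104) or mouse wt_3m_467 (0.131). It also ended with the mean of all probe sets of a gene (0.0770). Calls that held with a changed median without mouse Q92_18m_66 were proteasome (0.09, against 0.16), microglia (-0.78), MHC class I and interferon (-0.90, against -0.52), oligodendrocyte precursor (-0.40, against -0.21) and cortical (0.88, against 0.51). Without mouse Q92_18m_25 the medians were -0.59 for immediate early genes, -0.26 for microglia and -0.33 for MHC class I and interferon. The MHC median was -0.94 without mouse wt_18m_9, the direct pathway median -0.30 without mouse Q92_3m_439, and the immediate early gene median -0.24 without mouse wt_3m_438. The vascular median was -0.28 without mouse Q92_18m_11, the choroid plexus median -1.32 without mouse wt_18m_17, and the cortical median 0.27 without mouse wt_3m_436 and 0.17 without mouse Q92_3m_439.

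Across the 18193 genes represented by 1 probe set each, the genotype differences at 3 and 18 months had a Pearson correlation of -0.012 (jackknife SE 0.229 over arrays) and a Spearman correlation of -0.086. The correlation is across genes, which are not independent replicates. The 3 genes that were higher at 18 months (Speer4cos, Abhd1 and Rrs1) had the same sign at 3 months. Of the 11 genes that were lower at 18 months by their brightest probe set, 4 had the same sign at 3 months, with a median of 0.06 there against -1.26 at 18 months (camera p = 0.0868, and p = 0.458 with an estimated correlation).

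Ageing in wild-type striatum was described by comparing 18 with 3 months. The genes that passed were all higher in the old mice. Cd52, a surface glycoprotein of leukocytes, rose 5.02-fold (6.99 ± 0.56 against 4.66 ± 0.20), and Gfap, the intermediate filament of astrocytes, rose 3.64-fold (8.54 ± 0.13 against 6.67 ± 0.46). The ciliary gene Cfap54 rose 3.93-fold and the matrix gene Efemp1 rose 2.57-fold.

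In limma 23 probe sets passed (18 genes), all of them higher at 18 months, and 4757 reached an unadjusted p under 0.05. The log2 increases were 2.33 for Cd52 (SE 0.29, adjusted p = 0.0242), 1.97 for Cfap54 (adjusted p = 0.0223), 1.86 for Gfap (SE 0.26, adjusted p = 0.0304) and 1.36 for Efemp1 (adjusted p = 0.0304). Those of the transcription factor genes Elk3 and Nfe2l2 were 0.88 (adjusted p = 0.0223) and 0.78 (adjusted p = 0.0279), and that of Irak3, a brake on Toll-like receptor signalling, was 0.88 (adjusted p = 0.0304). Ctnnal1 and the magnesium transporter gene Magt1 rose by 0.87 each (adjusted p = 0.0279 and 0.0304), the lysophospholipid acyltransferase gene Lpcat2 rose by 0.82 (adjusted p = 0.0304) and the oligodendrocyte gene Aspa rose by 0.70 (adjusted p = 0.0485). Sex as a covariate and the 18S control as a covariate each gave 0 probe sets (lowest adjusted p among the named genes 0.0643 and 0.0511). Quantile normalisation gave 7, all among the 23, only the 6 arrays compared gave 7, of which 3 were among the 23, and the choroid plexus list as a covariate gave 9. Of the 11 named genes 7, 11 and 7 lost their calls in these 3 settings, in that order (adjusted p from 0.0503 to 0.204). Gfap also lost its call with an intensity trend and robust prior (0.0512). The count was 0 without mouse wt_3m_436, 2 without mouse wt_18m_12, 3 without mouse wt_3m_467 and 5 without mouse wt_3m_438, and of the 11 named genes 11, 10, 10 and 9 lost their calls, as did 8 without mouse wt_18m_17 and 5 without mouse wt_18m_9. The labels gave no hybridisation dates, so age and any batch of arrays cannot be told apart.

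**Figure D4:**
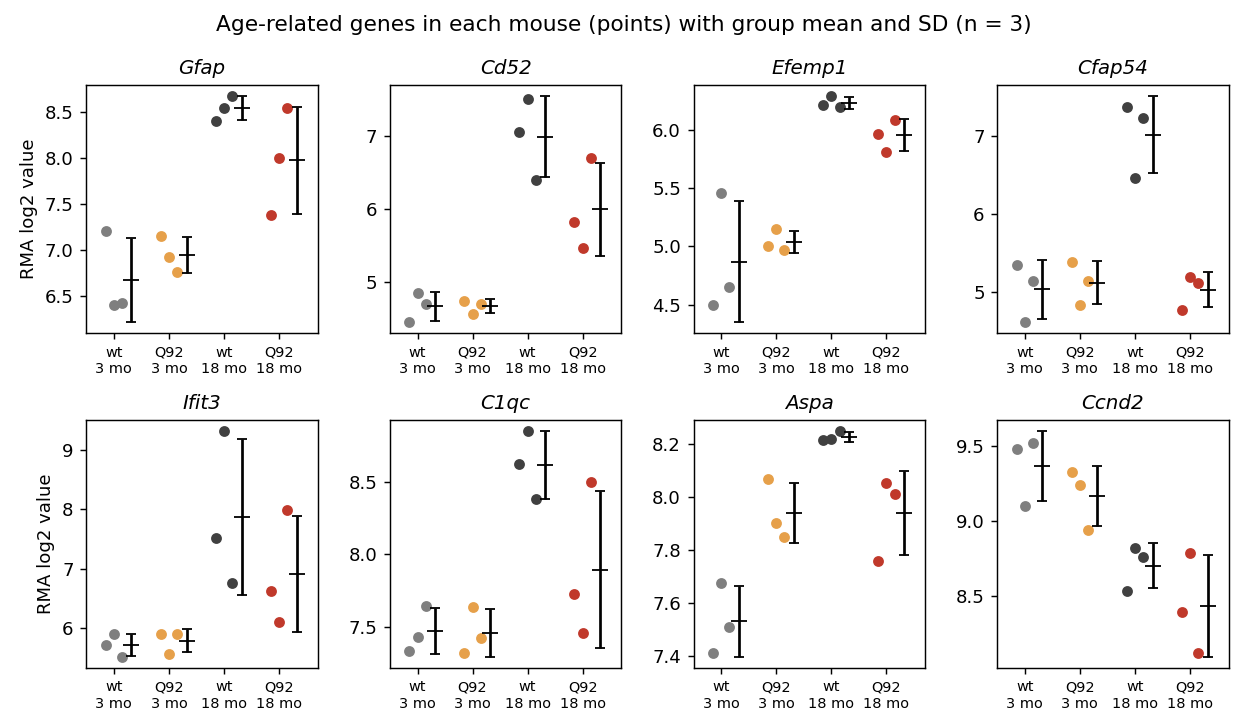
Log2 signal (y axis, RMA) of 8 genes in each mouse, by group (x axis); points are mice, horizontal bars group means and vertical lines 1 SD, n = 3. Gfap, Cd52, Efemp1, Cfap54 and Aspa were higher in all 3 wild-type mice at 18 months than in all 3 at 3 months, and Cfap54 read 5.03 ± 0.22 in Q92 mice at 18 months.

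Of the gene lists, 7 passed with the preset correlation in wild-type ageing, 5 higher and 2 lower. None held with an estimated correlation. All 17 genes of MHC class I and the interferon response were higher at 18 months (median 1.30, camera adjusted p = 9.54e-15, and adjusted p = 0.382 with an estimated correlation), none past the threshold over all probe sets and 14 adjusted over the list alone. The largest were the interferon-induced Ifit3 (2.16, adjusted p = 0.236), Usp18 (2.09, adjusted p = 0.237) and Ifit1 (1.85, adjusted p = 0.325) and the class I gene H2-D1 (1.71, adjusted p = 0.107). Microglia genes were higher in 18 of 19 (median 0.78, adjusted p = 1.25e-14, and adjusted p = 0.382 with an estimated correlation), 0 over all probe sets and 14 adjusted over the list alone, among them Ctss (1.24, adjusted p = 0.167) and C1qc (1.14, adjusted p = 0.134). Reactive astrocyte genes were higher in 12 of 14 (median 0.52, adjusted p = 1.15e-07, and adjusted p = 0.382 with an estimated correlation), with Gfap past the threshold and 9 adjusted over the list alone. Oligodendrocyte genes were higher in 16 of 17 (median 0.20, adjusted p = 2.97e-05, and adjusted p = 0.567 with an estimated correlation), with Aspa past the threshold and 2 adjusted over the list alone. Astrocyte genes were higher in 13 of 16 (median 0.13, adjusted p = 0.00140, and adjusted p = 0.524 with an estimated correlation), 1 of them adjusted over the list alone. Genes of neurogenesis and proliferation were lower in 15 of 18 (median -0.34, adjusted p = 6.35e-04, and adjusted p = 0.524 with an estimated correlation), 2 of them adjusted over the list alone, with Ccnd2 at -0.67 (adjusted p = 0.242) and Sox4 at -0.65 (adjusted p = 0.217). Projection neuron genes were lower in 26 of 33 (median -0.11, adjusted p = 0.0270, and adjusted p = 0.890 with an estimated correlation), 0 over all probe sets and 0 adjusted over the list alone. Without mouse wt_3m_467, 4 lists passed and those for projection neurons (adjusted p = 0.548), astrocytes (0.0596) and oligodendrocytes (0.0934) did not. The projection neuron call also ended without mouse wt_18m_12 (0.288) or wt_3m_438 (0.0550) and the neurogenesis call without mouse wt_3m_436 (0.247), and 11 lists passed without mouse wt_18m_9. Without mouse wt_18m_17 the median was 0.85 for MHC class I and interferon, with Ifit3 at 1.43 and Ifit1 at 0.99, 0.34 for reactive astrocyte and -0.18 for neurogenesis and proliferation genes. The projection neuron median was -0.22 without mouse wt_3m_436 and the oligodendrocyte median 0.32 without mouse wt_3m_438.

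Ageing in Q92 striatum was described in the same way, and more probe sets were lower than higher at 18 months. Penk fell 2.46-fold (10.37 ± 0.20 against 11.67 ± 0.08), Scn4b fell 3.76-fold, Ryr1 fell 4.26-fold and the activity-regulated transcription factor gene Egr2 fell 4.31-fold. Kcnj9, which encodes a potassium channel subunit, rose 3.94-fold (8.07 ± 0.12 against 6.09 ± 0.42).

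In limma 93 probe sets passed, 19 higher (16 genes) and 74 lower (54 genes), and 4763 reached an unadjusted p under 0.05. The largest log2 decreases were -2.17 for Sdr39u1 (adjusted p = 5.71e-04), -2.11 for Egr2 (adjusted p = 0.0259), -2.09 for Ryr1 (adjusted p = 0.00360), -1.91 for Scn4b (adjusted p = 0.0123), -1.61 for Gm6556 (adjusted p = 0.0175) and -1.56 for Clspn (adjusted p = 5.71e-04). Myo3b (-1.47), the arginase gene Arg2 (-1.38), Penk (-1.30, adjusted p = 5.71e-04) and Ddit4l (-1.28, adjusted p = 0.00989) followed. The increases were 1.98 for Kcnj9 (adjusted p = 0.0403), 0.97 for the B cell adaptor gene Blnk (adjusted p = 0.0259), 0.93 for Eya4 (adjusted p = 0.0175), 0.92 each for Tmem196 and Vwa5b2, 0.76 for the interferon gamma receptor gene Ifngr2 (adjusted p = 0.0175), 0.69 for 1700019D03Rik and 0.59 for Anxa7. Of the 93, 12 were also among the 24 that differed between genotypes at 18 months, all in the same direction, which the 3 Q92 arrays at 18 months that both comparisons use favour, including those of Penk, Ryr1, Ddit4l, Neto2 and Lmo2. With wild-type ageing 1 was shared (0.0475 expected by chance), by a probe set that matches several genes. The difference between the 2 age effects is the same quantity as the change of the genotype difference with age, for which 0 probe sets passed. The count was 7 without mouse Q92_3m_440, 15 without mouse Q92_3m_439, 21 without mouse Q92_18m_66, 31 without mouse Q92_18m_11 and 55 without mouse Q92_3m_466. It was 17 with the cortical and thalamic lists as covariates, 29 with only the 6 arrays compared, and 195 with the 18S control as a covariate. Of the 21 named genes that passed, the calls of 16, 16, 14, 13 and 8 ended without those 5 mice in that order and of 5 without mouse Q92_18m_25. The calls of 17 ended with the cortical and thalamic covariates, of 11 with only the 6 arrays compared and of 6 with sex as a covariate. Penk, Clspn and Sdr39u1 passed without any single array.

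Of the gene lists, 14 passed with the preset correlation in Q92 ageing, 7 higher and 7 lower. Only the indirect pathway list held with an estimated correlation. All 33 projection neuron identity genes were lower (median -0.76, camera adjusted p = 1.21e-39, fry adjusted p = 0.0139, and adjusted p = 0.135 with an estimated correlation), 8 of them past the threshold over all probe sets (Pde1b, Rgs9, Arpp21, Scn4b, Strn, Ryr1, Rasgrp2 and Gpr83) and all 33 adjusted over the list alone. Indirect pathway genes were lower in 5 of 6 (median -0.78, adjusted p = 9.46e-06, and adjusted p = 0.0360 with an estimated correlation), with Penk and Gpr6 past the threshold and 4 adjusted over the list alone. Direct pathway genes were lower in 6 of 9 (median -0.05, adjusted p = 0.0171, and adjusted p = 0.474 with an estimated correlation), 3 of them adjusted over the list alone. Immediate early genes were lower in 18 of 20 (median -0.48, adjusted p = 2.72e-07, and adjusted p = 0.474 with an estimated correlation), with Egr2 past the threshold and 6 adjusted over the list alone. The MHC class I and interferon genes were higher in 17 of 17 (median 0.63, adjusted p = 1.38e-04, and adjusted p = 0.475 with an estimated correlation), 2 of them adjusted over the list alone, and cortical neuron genes were higher in 12 of 15 (median 0.60, adjusted p = 0.00630, and adjusted p = 0.475 with an estimated correlation). The other lists that passed were proteasome (median 0.14), oxidative phosphorylation (0.09), cholesterol biosynthesis (0.08), microglia (0.24) and reactive astrocyte (0.29) upwards, and oligodendrocyte (-0.10), vascular (-0.18) and neurogenesis and proliferation (-0.14) downwards, with adjusted p from 0.474 to 0.540 with an estimated correlation. The microglia median turned to -0.06 without mouse Q92_18m_66 (adjusted p = 0.842), and without that mouse direct pathway (0.145), oxidative phosphorylation (0.412) and reactive astrocyte (0.377) did not pass either. Calls also ended without mouse Q92_18m_11 (oligodendrocyte 0.227, cortical 0.361, cholesterol 0.263, neurogenesis 0.0559), mouse Q92_18m_25 (vascular and cortical 0.102 each, cholesterol 0.0887), mouse Q92_3m_440 (direct pathway 0.109, cholesterol 0.0714, reactive astrocyte 0.0764) and mouse Q92_3m_466 (oxidative phosphorylation 0.0537, reactive astrocyte 0.0622). Without mouse Q92_18m_11 the oligodendrocyte median turned to 0.02 and the cortical median was 0.32. The MHC class I and interferon median was 0.21 without mouse Q92_18m_66 (adjusted p = 0.0488). Without that mouse the medians were also 0.05 for proteasome, 0.13 for cholesterol biosynthesis, -0.23 for oligodendrocyte and -0.24 for neurogenesis. Without mouse Q92_18m_25 they were -0.09 for direct pathway, 0.14 for oxidative phosphorylation, 0.47 for microglia, -0.16 for oligodendrocyte and -0.22 for neurogenesis. The direct pathway median was -0.19 without mouse Q92_18m_11, -0.15 without mouse Q92_3m_439 and -0.12 without mouse Q92_3m_466. The oligodendrocyte median was -0.06 without mouse Q92_3m_439, and the neurogenesis median was -0.25 without mouse Q92_3m_440.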

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

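The counts over other splits of the mice were set in advance, and the tests of the neighbourhood of Htt, of other tissue, of the 18S control and of cell shares were chosen only after the result was seen. Groups of 3 mice are too small for a test of single outlying mice, so none was made.

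By the test of the change with age itself, with the preset correlation, the genotype difference was lower at 18 than at 3 months in 12 gene lists and higher in 2. Of these 14 lists only the indirect pathway list passed with an estimated correlation (adjusted p = 0.0247), and for the other 13 adjusted p = 0.220 to 0.410 with an estimated correlation. The medians of the change were -0.68 for projection neuron identity, -0.84 for indirect pathway neuron, -0.20 for direct pathway neuron, -0.38 for activity-regulated immediate early genes, -0.26 for astrocyte, -0.35 for reactive astrocyte, -0.42 for microglia, -0.52 for MHC class I and interferon response, -0.42 for oligodendrocyte, -0.21 for oligodendrocyte precursor, -0.18 for vascular and -0.87 for choroid plexus and ependyma. The medians of the 2 that were higher were 0.16 for proteasome and 0.51 for cortical excitatory neuron. Of 100 splits drawn from the 200 possible ones, 4 gave at least 14 lists, the real one included, and the highest of the others gave 15. The share over all 200 splits is not known, so chance is not excluded for the number of lists. The splits exchange genotypes within each age, so they address a genotype difference at either age and not its change with age alone. For the number of probe sets the real split gave 0 and the others up to 13, so that 100 of 100 splits gave as many by construction and this count says nothing about chance. Of the 14 calls 7 ended without single mice. These were choroid plexus without mouse Q92_3m_439 (adjusted p = 0.245) or wt_18m_12 (0.313), cortical without mouse Q92_18m_11 (0.234) or Q92_18m_25 (0.0516), MHC class I and interferon without mouse wt_18m_17 (0.299), and immediate early genes without mouse Q92_18m_66 (0.196). The others were direct pathway without mouse Q92_18m_66 (0.0672) or Q92_3m_440 (0.0518), reactive astrocyte without mouse wt_18m_17 (0.0570) or Q92_18m_25 (0.0924), and oligodendrocyte precursor without mouse Q92_18m_11 (0.0573), Q92_18m_25 (0.104) or wt_3m_467 (0.131).

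An 18S ribosomal RNA control probe set, left out of the comparisons, read higher by 1.64 in Q92 than in wild-type mice at 18 months (7.35 ± 1.06 against 5.71 ± 0.06, n = 3), and read 8.28 ± 2.52 against 6.89 ± 1.72 at 3 months. The 2 further 18S probe sets differed by 0.63 (7.24 ± 0.75 against 6.61 ± 0.06, n = 3) and 0.60 (5.88 ± 0.61 against 5.28 ± 0.18, n = 3) at 18 months, and in both mouse Q92_18m_25 lay below at least 1 wild-type mouse.

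Of the 5 genes that passed between the genotypes at both ages, the 4 on the chromosome of Htt may reflect DNA of another strain carried along with the targeted Htt allele. The 401 measured genes centred on Htt held 9 genes with an unadjusted p under 0.001 for the age-averaged genotype difference (Speer4cos, 2700038G22Rik, Smarcd3, Galnt11, Abhd1, Atraid, Mrpl33, Ppp1cb and Jakmip1), against at most 2 in any of 34 other windows of that size, and 33 genes reached it among the 18032 placed. Genes were counted by their brightest probe set, and the 9 include 4 of the 5 genes. For Ppp1cb that probe set (-0.45) moved opposite to the one that passed at both ages. Of the 5, 4 lie on the chromosome of Htt, which holds 6.22% of placed genes (Fisher's exact test, one-sided, p = 7.09e-05), and this argues against an effect of the allele that is independent of position for these 4 and leaves Rrs1, on another chromosome, open. Speer4cos and Abhd1 have no other probe set of their own, and of the 7 of the other genes 42.9% moved the same way at an unadjusted p under 0.05 in limma for the age-averaged difference, namely 2 of the 3 of Jakmip1 (-0.94 and -0.44) and the 1 of Rrs1 (0.49), but none of the 3 of Ppp1cb, of which 1 moved the opposite way (-0.45). For the 5 genes as a set, a difference in expression and a mismatch of single probe sets to another strain's sequence cannot be told apart without the probe sequences, and the labels give C57BL/6 for all mice and no donor strain of the targeted allele.

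For the lower projection neuron genes in Q92 mice at 18 months, the median with the cortical and thalamic list means as covariates was -0.71, against -0.65 without them (with them, fry adjusted p = 0.00670, and camera adjusted p = 0.0660 with an estimated correlation). The size of the median and fry argue against tissue from those regions as the whole cause, while camera with an estimated correlation did not pass. With the 18S control as a covariate the median was -0.52 and the call ended (fry adjusted p = 0.119, against 0.0331 without it). The list mean went from -0.71 (SE 0.169) to -0.61 (SE 0.170). The indirect pathway list passed with a median of -0.80 (fry adjusted p = 0.00287). For the indirect pathway genes this argues against an effect of that signal that is alike at both ages as the whole cause. The control varied mostly among the 3-month mice (SD 2.52 in Q92 and 1.72 in wild type, against 1.06 and 0.06 at 18 months). An effect confined to 18 months would therefore remain in this fit. For the projection neuron difference RNA or labelling quality cannot be told apart from genotype, since that control differed between the genotypes. The 2 further 18S probe sets and the actin and Gapdh contrasts of 3' against 5' probe sets (differences of -0.00526 and 0.0171) overlapped between the genotypes. At 3 months that control differed by 1.40, with overlapping mice, while the projection neuron list mean read 0.23 ± 0.17 in Q92 and 0.24 ± 0.17 in wild-type mice. A smaller share of projection neurons would raise the markers of other cells, whereas the glial and vascular mean differed by -0.22 (SE 0.0964, 95% confidence interval -0.44 to 0.00, exact permutation p = 0.2, two-sided). The upper limit of 5.24e-05 left almost no rise in that interval, but the interval was not entirely negative. A smaller share, as the whole or as part of the cause, is therefore left open. The comparison also assumes that expression within those other cells did not differ. Lower expression in each projection neuron was not tested by these arrays of whole tissue.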

How the results depend on the processing

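Blocking by age in days, the 18S, cortical and thalamic, and choroid plexus covariates and the removal of both arrays with the lowest mean correlation (Q92_18m_66 and wt_3m_467) were chosen only after the result was seen. Mice were not paired by number, since no animal number is shared between groups. Both genotypes hold mice of 100 and of 103 days at 3 months and of 596 days at 18 months, so the genotype comparisons were also blocked by age in days, which leaves 4 residual degrees of freedom and, at 18 months, a comparison of 2 wild-type mice with 1 Q92 mouse that is assumed to vary like the others (median SE 0.184 against 0.122). The comparisons between ages cannot be blocked, since no day is shared between the ages. Leaving out an array leaves 2 mice in its group, whose spread is taken from all groups. An alternative for values on a linear scale was not run, since the values are log2. Signal over background was not measured, and leaving out dim probe sets gave counts of 20, 5, 0, 22 and 98 for the genotype difference at 18 months, at 3 months, its change with age, ageing in wild type and ageing in Q92. Of the calls of single genes named in the text, 316 held and 67 were lost over the alternatives set in advance, 122 and 86 over the later ones, and 130 and 158 without single arrays. The calls of gene lists held in 110 and were lost in 98 cases over the alternatives set in advance, held in 26 and were lost in 5 when blocked, and held in 341, were lost in 54 and turned by camera's direction in 1 without single arrays. The correlation of the genotype differences across genes stayed near 0 (0.00587 with sex as a covariate, -0.0215 when blocked, -0.17 to 0.09 without single arrays). For the changes that follow the cause was not tested, except that testing 1 probe set per gene adjusts over fewer tests and a fit to only the arrays compared, or a blocked fit, has fewer degrees of freedom.

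The count of probe sets for the genotype difference at 18 months (24) was 45 with an intensity trend and robust prior, 56 with array weights, 37 with 1 probe set per gene, 11 with only the arrays compared, 8 with the 18S covariate, 108 with the cortical and thalamic covariates, 54 without both arrays, 4 when blocked (1 of them among the 24) and 9 to 25 without single arrays. At 3 months (5) it was 1 with only the arrays compared, 3 with 1 probe set per gene, 3 with the 18S covariate, 3 without both arrays, 2 when blocked and 1 to 4 without single arrays. For the change with age (0 in limma, 2335 at an unadjusted p under 0.05) it was 3 with the trend, 2 with array weights, 3 with 1 probe set per gene, 1 with the cortical and thalamic covariates, 1 when blocked and 0 to 3 without single arrays. For ageing in wild type (23) it was 7 with quantile normalisation, 0 with sex as a covariate, 7 with only the arrays compared, 40 with array weights, 0 with the 18S covariate, 37 with the cortical and thalamic covariates, 9 with the choroid plexus covariate and 0 to 23 without single arrays. For ageing in Q92 (93) it was 29 with only the arrays compared, 195 with the 18S covariate, 17 with the cortical and thalamic covariates, 31 without both arrays and 7 to 87 without single arrays. The mice behind the ranges are named with each result above. The number of lists, with an estimated correlation and with fry, was 1 and 2 at 18 months (13), 0 and 0 at 3 months (4), 1 and 1 for the change with age (14), 0 and 0 for ageing in wild type (7) and 1 and 2 for ageing in Q92 (14). Without single arrays it was 8 to 17, 3 to 7, 12 to 16, 4 to 11 and 10 to 14 in the same order.

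Signs turned for values that had not passed over all probe sets. At 3 months, with the 18S covariate, the log2 differences were 0.00654 for Cnr1, 0.0150 for Drd2, -0.0610 for Grik3, 0.0257 for Penk, 0.13 for Rgs9 and 0.0316 for Tac1. Without both arrays they were 0.0358 for Cnr1, 0.0316 for Drd2, -0.11 for Grik3, 0.0253 for Penk, 0.11 for Rgs9 and 0.0288 for Tac1. With array weights they were 0.0201 for Cnr1, 0.0263 for Rgs9 and 0.0489 for Tac1, and with the choroid plexus covariate 0.0457 for Cnr1, 0.12 for Drd2, 0.0178 for Pdyn and 0.0296 for Tac1. Sex as a covariate gave -0.00339 for Pde10a and 0.0170 for Tac1, and the cortical and thalamic covariates gave -0.0226 for Pde10a and -0.0389 for Ppp1r1b. Those covariates also gave -0.12 for Sc5d and -0.00177 for Slc17a7 at 18 months, -0.0583 for Tbr1 in the change with age and -0.40 for Neurod6 in Q92 ageing, and the choroid plexus covariate gave 0.28 for Kcnj13 in the change with age. Htt in wild-type ageing was 0.00341 with a median shift, 0.0198 with the cortical and thalamic covariates and 0.0686 without both arrays. Blocking gave 0.48 for Chrm4 at 18 months. For lists at 3 months it was the direction of the test that turned from camera's upward one. With fry it was downward for projection neurons (median -0.0240) and the indirect pathway (-0.00777), whose medians were the same as reported. Camera's own direction was downward for the indirect pathway when blocked (median -0.00777) and with sex as a covariate (-0.0240). With the mean of all probe sets of a gene it was downward for the indirect (-0.0351) and the direct pathway (-0.0291).

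Without single arrays the 3-month values ran from -0.24 to 0.0922 for Cnr1, -0.17 to 0.0316 for Drd2, -0.28 to 0.00174 for Gpr6, -0.11 to 0.19 for Grik3, -0.19 to 0.17 for Pde10a, -0.13 to 0.00668 for Pdyn, -0.0877 to 0.0253 for Penk, -0.0883 to 0.16 for Ppp1r1b, -0.12 to 0.11 for Rgs9, -0.0370 to 0.26 for Ryr1, -0.00793 to 0.31 for Slc22a8 and -0.13 to 0.0879 for Tac1. The 3-month list medians ran from -0.11 to 0.11 for projection neurons, -0.0965 to 0.00320 for the indirect and -0.00376 to 0.11 for the direct pathway. Ranges in other comparisons were -0.0690 to 0.60 for Sc5d and -0.25 to 0.44 for Srebf2 at 18 months, -1.44 to 0.0455 for Ifit1 in the change with age, -0.13 to 0.77 for Chrm4 and -0.0544 to 0.0686 for Htt in wild-type ageing, and -0.0604 to 0.47 for the microglia list in Q92 ageing, which was the 1 list call whose camera direction turned (without mouse Q92_18m_66). The median alone turned for oligodendrocyte in Q92 ageing (0.0157 without mouse Q92_18m_11) and for vascular at 3 months (-0.00793 without mouse wt_3m_436), and both calls were lost.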

Other observations

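The tests of the pathway contrast were chosen only after the result was seen, and the counts over other splits of the mice were set in advance.

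Of the probe sets that rose with age in wild-type mice, 2 were also lower in Q92 than in wild-type mice at 18 months, and they belong to Cfap54 and Parp3. Both comparisons use the same 3 wild-type arrays at 18 months, so high values in those arrays alone would give both differences. Cfap54 read 7.01 ± 0.49 in wild-type mice at 18 months and 5.03 ± 0.22, 5.04 ± 0.37 and 5.12 ± 0.28 in Q92 mice at 18 months, wild-type mice at 3 months and Q92 mice at 3 months. For Parp3, named after its values were seen, the log2 differences were 1.00 with age in wild type and -0.75 between genotypes at 18 months. The change of the genotype difference with age did not pass for either (adjusted p = 0.300 for Cfap54 and 0.615 for Parp3).

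A hypothesis is that neurons of the indirect pathway are affected more than those of the direct pathway in Q92 mice at 18 months. The mean of the indirect minus the mean of the direct pathway genes, a difference taken within each array, differed between the genotypes by -0.41 (SE 0.05, 95% confidence interval -0.53 to -0.29, exact permutation p = 0.1, two-sided), with all 3 Q92 mice below all 3 wild-type mice. At 3 months the difference was -0.12 (95% confidence interval -0.23 to 0.00, exact permutation p = 0.1, two-sided). Both p are the smallest that 3 mice against 3 allow, and the data may reflect a difference between the pathways, between the genes chosen for the 2 lists, or both.

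With 3 mice against 3 there are 10 splits, too few for a share under 0.05. At 18 months the genotype comparison gave 24 probe sets and 13 lists, and the highest of the other splits gave 31 and 15, so that 2 splits gave as many in each case. The split with 31 set mice wt_18m_9, Q92_18m_11 and Q92_18m_25 against the others. At 3 months it gave 5 probe sets and 4 lists, with 0 and 7 in the highest other, as many in 1 and in 7 splits. Ageing in wild type gave 23 and 7, with 4 and 11 in the highest other, as many in 1 and in 6 splits. Ageing in Q92 gave 93 and 14, with 0 and 11 in the highest other, as many in 1 split each.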
